A study of Homo sapiens with 8 samples.

How the data were processed

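RNA was measured in 8 libraries of 2 human squamous carcinoma lines, A431 and CAL27, each with 2 DMSO and 2 NEDD8i libraries collected after 16 h of treatment. Per the labels' protocols, cells were grown below confluence, the compounds were added with fresh medium, lysates in RLT plus buffer went over a shredding column, and RNA was extracted with an RNeasy Plus kit. Libraries were made with a QuantSeq FWD kit, per the labels' protocols, which primes on poly(A) tails and reads the 3' ends of transcripts. The labels name the inhibitor only as NEDD8i. Its identity and dose, the media, and whether replicates were separate cultures are not given in the sources used here.

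The deposited values are whole-number counts of reads per gene, 1 table per library. Per the submitters' processing notes, reads were aligned to GRCh38 with STAR, whose version is not given in the sources used here. Per the file headers, a filtered alignment was counted with featureCounts 2.0.8 over the exons of the basic GENCODE 39 annotation. The filter itself is not given in the sources used here. The header command set paired-end mode without the option for counting fragments, so each mate of a pair counts once. Of the gene counts from 1 to 40 in a library, 70.2% to 76.7% were even. Counts are therefore not independent molecules, and counting errors taken from them are too small. Counting ignored strand, per the file headers, although the kit keeps it, so reads of a gene and of an antisense gene over the same bases could not be told apart. The options for multi-mapping reads and for reads over more than 1 gene were not set, so such reads were dropped. Genes with near-identical copies and genes whose exons overlap those of others are therefore undercounted or uncertain. The submitters' processing notes also list DESeq2, whose results were not used here.

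The tables hold 61533 gene identifiers, of which 61369 matched a symbol in a table of gene names, and 1196 identifiers whose symbol also stood on another identifier with more counts kept their identifier as name. Coordinates are from the count tables and refer to GRCh38, from the start of the first exon to the end of the last. Gene types came from an older GENCODE release. For each gene the share of exonic bases inside exons of other genes on either strand was computed with GenomicRanges 1.54.1. CPM, the counts per library size, were computed here from the deposited counts, with library sizes scaled by TMM factors.

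The A431 libraries held 57327373 and 51272416 counts under DMSO and 49037868 and 58461295 under NEDD8i. The CAL27 libraries held 50713295 and 62509817 counts under DMSO and 53988181 and 59386972 under NEDD8i. In a single library 3 counts are 0.048 to 0.0612 CPM before TMM scaling. The 10 genes with most counts took 5.46% to 5.83% of a library. Replicates were compared first. Their counts differed by 6.55 to 14.2 times sampling noise (chi-square over its degrees of freedom), and their log2 CPM correlated across genes with r = 0.981 to 0.986, so no library was a copy of another.

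Differences were tested with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood tests on the counts, after filtering low genes with filterByExpr, which left 18738 genes. A single fit gave a mean to each of the 4 groups, with 4 residual degrees of freedom, 12.3 prior degrees of freedom and a common biological coefficient of variation of 0.0852. Contrasts were NEDD8i against DMSO in each line, the CAL27 response minus the A431 response, and CAL27 against A431 under DMSO. P-values were adjusted by Benjamini and Hochberg over all genes tested, with calls at adjusted p under 0.05. Overlaps between the lines were tested by Fisher's exact test, one-sided. Where a group had 0 counts, the fold was computed against 3 counts over the group's libraries on the TMM scale. It is a lower bound for counting error only, and only if counts were independent. With each mate counted, a floor of 3 counts is too low and such bounds are too large.

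A total of 39 gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. They hold the pathways of NEDD8, SUMO and cullin-RING ligases, stress responses, cell cycle, inflammation, epithelial state, growth factors, lipid synthesis, protein production and markers of other cell types. Each list with at least 4 tested members, 37 in all, was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Beside it stand camera with a correlation estimated from the 8 libraries, and fry. Adjustment was over the lists within a contrast. Some lists share members, such as SLC7A11 in NRF2 targets and the integrated stress response, so their calls are not independent. For the lists in each line, and for those called for the difference, the text gives the members called over all genes tested and those called when adjusted over the list alone.

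The text names NEDD8, NAE1, UBA3 and UBE2M first. It then names, per line, the 10 largest rises and 10 largest falls among called genes with a mean of at least 10 CPM in a group of the contrast and no overlap between NEDD8i and DMSO libraries. For both lines together it names the 5 shared rises and 5 shared falls with the largest smaller change, and for the difference of responses and for the DMSO contrast the 5 largest of each sign. For each list it names up to 4 members with the smallest p. List members named because 5 or fewer moved in that direction were chosen after their values were seen. XIST, TSIX and Y-linked genes were left out of naming. Results of 1 gene list and of 5 genes that fall under these rules are not reported here.

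The tests were checked on simulated counts drawn from the real means of each line, with 50 genes changed at each of 4 sizes, as many up as down. In the data 43.6% of tested genes were called in A431 and 49.6% in CAL27. The simulation therefore did not test the scaling under so many changes, and its shares of false calls need not hold for the data. In the simulated A431 contrast, over 17925 genes, 39, 45, 47 and 50 genes were recovered at 1.5, 2, 4 and 8-fold, and 5.73% of the calls were false. In the simulated CAL27 contrast, over 17926 genes, 36, 41, 47 and 50 were recovered and 6.45% were false. With each fragment entered as a pair of counts, 35, 41, 47 and 48 were recovered in A431 over 17948 genes with 1.72% false, and 36, 39, 49 and 50 in CAL27 over 17942 genes with 3.87% false. A shift of 0.5 on the log2 scale in proteasome subunits of the A431 contrast, over 17936 genes, was called by camera, with 0 calls among 35 other lists. Genes were drawn independently of each other, so this check cannot show false calls that come from correlation within a list.

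Results were recomputed with DESeq2 size factors, with upper-quartile factors, without a filter, with at least 1 CPM in all libraries of a group, with DESeq2 1.42.0, with limma voom, with only the libraries compared, with the replicate number as a block, and without each library in turn. DESeq2 and voom were run for genes and not for lists, and the fit of only the libraries compared was not run for the difference. A further alternative, with counts divided by 2 and rounded up, was chosen after seeing the data. Smooth trends were fitted with mgcv 1.9.3, and plots were drawn with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.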

Results

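Gene expression was measured by RNA sequencing in 2 human squamous carcinoma lines, A431 (an epidermoid carcinoma of skin) and CAL27 (a carcinoma of the tongue). Each line received DMSO, the solvent control, or an inhibitor labelled NEDD8i for 16 h, which gave 4 groups of 2 libraries. The comparison within each line asks which transcripts change when the pathway of NEDD8, a ubiquitin-like protein, is inhibited. The 8 libraries held 49037868 to 62509817 counts each, and 19681 to 23822 genes had a count in a library. The mitochondrial genome gave 2.69% and 3.15% of the counts in the A431 DMSO libraries and 1.96% and 2.27% under NEDD8i. In CAL27 the shares were 1.77% and 1.56% under DMSO and 1.45% and 1.02% under NEDD8i. On the log2 scale of CPM (counts scaled by library size), the first principal component held 62.8% of the variance and separated the lines, and the second held 19.6% and separated NEDD8i from DMSO in both. Log2 fold changes are NEDD8i against DMSO, with 2 libraries per group, and levels are CPM ± SD (n = 2). The ± after a log2 change or difference is an approximate standard error. It is the absolute value divided by the square root of the F statistic of the quasi-likelihood test. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Counting intervals and floors cover counting error only and take counts as independent. Intervals are thus too narrow and floors too low where both mates of a pair were counted.

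Of NEDD8, NAE1, UBA3 and UBE2M, only UBE2M was called in both lines. NEDD8 (ENSG00000129559.13, chromosome 14, 24216857 to 24232367 on GRCh38) stood at 48.1 ± 0.336 CPM under DMSO and 51.8 ± 0.958 under NEDD8i in A431, a log2 change of 0.11 ± 0.07 that did not pass the test (edgeR adjusted p = 0.217). It rose from 39.2 ± 0.451 to 52.1 ± 0.0968 CPM in CAL27, by 0.41 ± 0.07. Exons of other genes cover 22.7% of its exonic bases, and reads over shared exons were left out of the counts. UBE2M, the E2 enzyme that passes NEDD8 to cullins, rose by 0.79 ± 0.06 in A431 and 0.72 ± 0.06 in CAL27. NAE1, a subunit of the NEDD8-activating enzyme, rose by 0.69 ± 0.06 in A431 and had a log2 change of -0.01 ± 0.06 in CAL27, and the difference of -0.71 passed the test (edgeR adjusted p = 1.02e-05). UBA3, the catalytic partner of NAE1, had changes of -0.09 and -0.02 that did not pass.

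In A431, NEDD8i raised NRF2 targets, the only list whose call also held with an estimated correlation. Of 18738 genes tested, 4224 were higher and 3951 lower, and 1027 and 1485 of these changed at least 2-fold. AKR1B10, an aldo-keto reductase (ENSG00000198074.10, chromosome 7, 134527567 to 134541412), went from 1.3 ± 0.223 to 575.2 ± 6.34 CPM, a 438-fold rise (log2 8.78 ± 0.11, edgeR adjusted p = 6.34e-19). CXCL8, which attracts neutrophils, rose 246-fold from 0.347 ± 0.271 to 88.3 ± 1.64 CPM. Its log2 rise of 7.94 became 9.14 without A431 DMSO replicate 1 and 7.35 without replicate 2. F2RL2, a protease-activated receptor, had 0 counts in both DMSO libraries and 1042 under NEDD8i, and so was at least 376-fold higher with the floor set at 3 counts over the group.

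Other large rises in A431 were smaller. HKDC1, a hexokinase-like protein, rose 72.7-fold and the lipase-related PNLIPRP3 57-fold. SPP1, which encodes osteopontin, rose 51-fold to 1044 ± 23.8 CPM, CYP4F3, a leukotriene hydroxylase, 49.9-fold, MAP2, a microtubule-associated protein, 31.2-fold and TSPAN7, a tetraspanin, 26.9-fold. Without A431 DMSO replicate 2 the log2 rise of HKDC1 was 7.05 (6.18 with it), and that of TSPAN7, 4.75, was 6.37 without replicate 1 and 4.04 without replicate 2. Other genes' exons cover 37.7% of the exonic bases of TSPAN7 and 10.9% of those of CYP1B1, which fell. Among the falls, the transcription factor ATOH8 dropped from 33 ± 0.252 to 0.313 ± 0.0718 CPM (103-fold), PSAPL1 83.2-fold and MAP2K6, a kinase that activates p38, 39.3-fold. FAXDC2 fell 27.3-fold, HPGD, which inactivates prostaglandins, 20.3-fold, and the surface protein PSCA 16.7-fold. CYP1B1, a cytochrome P450, fell 16-fold, the ephrin receptor EPHA4 14-fold and SEMA6D, a semaphorin, 13.8-fold. Adjusted p for the 10 largest rises and 10 largest falls was at most 2.13e-08 by the edgeR quasi-likelihood test.

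NRF2 targets, which encode antioxidant and detoxifying enzymes, formed the list with the highest median change in A431. Of 27 members 26 rose and PIR fell, with the same counts adjusted over the list alone, and the median log2 change was 2.03 (camera adjusted p = 9.36e-18, and adjusted p = 0.0427 with an estimated correlation). AKR1C1, a steroid-reducing enzyme, rose 24.3-fold, TXNRD1, thioredoxin reductase, by 3.08 ± 0.03 and GCLM, of glutathione synthesis, by 2.51 ± 0.04. AKR1C1, AKR1C2 and AKR1C3 are near-identical copies, so their separate values are uncertain. HIF targets, genes of the hypoxia response, rose in 20 of 23 members and fell in 0 (also adjusted over the list alone), with a median of 1.36 (camera adjusted p = 4.55e-12, but adjusted p = 0.0742 with an estimated correlation). BNIP3 rose by 4.52 ± 0.06, VEGFA by 2.09 ± 0.05 and LDHA by 1.38 ± 0.04. Genes of the integrated stress response rose in 20 of 24 members and fell in 0, likewise adjusted over the list alone (median 1.12, camera adjusted p = 3.88e-09, adjusted p = 0.11 with an estimated correlation). SLC7A11, the cystine transporter and also a member of the NRF2 list, rose by 3.43 ± 0.06. STC2 rose by 3.07 ± 0.08 and TRIB3 by 2.01 ± 0.05.

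Cell cycle lists changed in different directions in A431, and no test compared them with each other. Of 28 G2/M genes 27 fell and 0 rose, also adjusted over the list alone (median -1.33, camera adjusted p = 3.32e-15, adjusted p = 0.108 with an estimated correlation). KIF20A stood at -2.92 ± 0.08, PLK1 at -2.32 ± 0.07, CDC20 at -2.05 ± 0.06 and TOP2A at -1.61 ± 0.04. Of 25 G1/S genes 17 rose and 5 fell (RRM1, TK1, POLA1, PRIM1 and UNG), with the same counts adjusted over the list alone (median 0.33, camera adjusted p = 0.00235, adjusted p = 0.11 with an estimated correlation). Cyclin E genes led, with CCNE1 up by 2.10 ± 0.11 and CCNE2 by 1.32 ± 0.10, and RRM2 rose by 0.77 ± 0.04. Replication-dependent histones fell in 9 of 14 members (10 adjusted over the list alone) and rose in 0 (median -2.29, camera adjusted p = 0.000198, adjusted p = 0.11 with an estimated correlation), H2AC6 by -3.07 ± 0.10 and H1-2 by -2.62 ± 0.14. These histones are near-identical copies, and most of their mRNA ends in no poly(A) tail. Replication licensing genes rose in 4 (CDC6, ORC6, MCM10 and CDC45) and fell in 6 of 21 members, also adjusted over the list alone (median 0.02, camera adjusted p = 0.732). CDC6 rose by 0.78 ± 0.04 and MCM2 fell by -0.55 ± 0.04. Targets of p53 rose in 14 and fell in 9 of 26 (15 and 10 adjusted over the list alone, median 0.53, camera adjusted p = 0.0583). The cell cycle inhibitor CDKN1A rose by 2.30 ± 0.05 and GDF15 by 2.88 ± 0.10.

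Immune lists were called in opposite directions in A431. Interferon-stimulated genes fell in 22 of 26 members and only USP18 rose (23 and 1 adjusted over the list alone, median -1.02, camera adjusted p = 3.49e-08, adjusted p = 0.052 with an estimated correlation). IFIT1 stood at -2.57 ± 0.11, IFIT2 at -1.94 ± 0.10 and IFIT3 at -1.70 ± 0.06. Antigen presentation genes fell in 11 of 14 and rose in 0, also adjusted over the list alone (median -0.48, camera adjusted p = 8.95e-05, adjusted p = 0.122 with an estimated correlation), led by the immunoproteasome subunit PSMB9 at -2.00 ± 0.06. NF-kB targets rose in 12 and fell in 6 of 25, also adjusted over the list alone. Their median was 0.52, or 1.56 over the 21 members with counts in every group. Their camera adjusted p of 0.0332 became adjusted p = 0.27 with an estimated correlation and 0.066 over genes with at least 1 CPM in a group. It was 0.07 with the 4 A431 libraries alone and 0.0507 with the replicate number as a block. Over 17 alternatives the list's adjusted p ranged from 0.000184 to 0.27. The lowest came from fry, which does not compare a list with other genes. The median was 1.23 without A431 DMSO replicate 1. IL1A rose by 2.53 ± 0.09 and TNFAIP3 by 2.15 ± 0.08, while TNFAIP2 fell by -1.88 ± 0.05.

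A further 4 lists were called higher in A431, each without holding at an estimated correlation. Ligands of the EGF receptor led a list of 10 in which 8 rose while EGFR and ERBB2 fell, also adjusted over the list alone (median 1.39, camera adjusted p = 0.00183, adjusted p = 0.11 with an estimated correlation): HBEGF by 3.49 ± 0.07, EREG by 3.06 ± 0.05 and AREG by 2.81 ± 0.09. Stress keratins and alarmins rose in 11 of 15 while S100A7 and LCN2 fell (11 and 4 adjusted over the list alone, median 0.87, camera adjusted p = 0.00298, adjusted p = 0.154 with an estimated correlation). KRT16 rose by 2.97 ± 0.06 and KRT6B by 2.07 ± 0.05. KRT6A, KRT6B and KRT6C share near-identical sequence. Matrix proteases and their regulators rose in 6 of 11 while MMP13 and PLAT fell, also adjusted over the list alone. Their median was 0.71, or 0.70 over the 10 members with counts in every group. The camera adjusted p was 0.0182, and adjusted p = 0.209 with an estimated correlation. PLAUR, the urokinase receptor, rose by 3.53 ± 0.06 and the collagenase MMP13 fell by -3.51 ± 0.16. That call was lost without A431 DMSO replicate 2 (median 0.59), without A431 NEDD8i replicate 1 (0.31), and without CAL27 NEDD8i replicate 1 or 2 (0.71 for each). Over 17 alternatives the list's adjusted p ranged from 2.87e-05 to 0.209. The lowest came from fry, which tests a list without comparing it with other genes. BCL2 family genes rose in 7 of 14 while BAK1 and BMF fell (9 and 2 adjusted over the list alone, median 0.57, camera adjusted p = 0.00509, adjusted p = 0.129 with an estimated correlation). PMAIP1, which encodes NOXA, rose by 1.20 ± 0.07 and BMF fell by -3.26 ± 0.21.

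Protein production and turnover genes also changed in A431. Proteasome subunits rose in 23 of 31 members and fell in 0, also adjusted over the list alone (median 0.24, camera adjusted p = 6.12e-06, adjusted p = 0.126 with an estimated correlation). Endoplasmic reticulum chaperones rose in 11 of 17 while HERPUD1, CALR and CRELD2 fell, likewise adjusted over the list alone (median 0.52, camera adjusted p = 0.00857, adjusted p = 0.367 with an estimated correlation). DNAJB11 rose by 0.97 ± 0.06 and calreticulin (CALR) fell by -0.90 ± 0.04. Ribosome biogenesis genes rose in 14 and NOP58 alone fell, of 19, also adjusted over the list alone (median 0.35, camera adjusted p = 0.00242, adjusted p = 0.233 with an estimated correlation). Cytosolic ribosomal protein genes fell in 34 of 51 and RPL14 rose (35 and 1 adjusted over the list alone, median -0.16, camera adjusted p = 0.000267, adjusted p = 0.27 with an estimated correlation). Cholesterol synthesis genes rose in 14 of 20 while LSS, INSIG1 and SREBF2 fell (14 and 4 adjusted over the list alone, median 0.57, camera adjusted p = 0.00235, adjusted p = 0.383 with an estimated correlation). MSMO1 rose by 0.96 ± 0.05 and SQLE by 0.75 ± 0.05. Other genes' exons cover 78.1% of the exonic bases of CYP51A1, a member of this list. These 18 lists of 37 tested were the ones called in A431, 13 higher and 5 lower, and NRF2 targets alone held with an estimated correlation.

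The lists of the modifier pathways themselves were not called in A431. Neddylation enzymes rose in 7 of 13 members while RBX1, RNF7 and SENP8 fell, with the same counts adjusted over the list alone (median 0.42, camera adjusted p = 0.166). Cullin-RING ligase components rose in 16 and fell in 8 of 30 (16 and 9 adjusted over the list alone, median 0.19, camera adjusted p = 0.134). KLHL21 rose by 0.90 ± 0.06 and CUL1 by 0.66 ± 0.06. In the COP9 signalosome GPS1, COPS2, COPS3, COPS7B and COPS8 rose and COPS6 and COPS7A fell of 10, also adjusted over the list alone (median 0.16, camera adjusted p = 0.173). The SUMO pathway rose in 7 of 17 while SUMO2, SUMO3, SAE1, PIAS1 and PIAS3 fell, also adjusted over the list alone (median 0.09, camera adjusted p = 0.23). Autophagy and lysosome genes rose in 7 of 18 while LAMP2, CTSD, NEU1 and ATP6V0D1 fell, likewise adjusted over the list alone (median 0.16, camera adjusted p = 0.166). GLA rose by 2.30 ± 0.06. Heat shock genes rose in 6 of 13 while HSPA1A, DNAJA1, HSPB1, HSPE1 and HSP90AA1 fell, again adjusted over the list alone too (median -0.02, camera adjusted p = 0.937), and HSPA1A has a near-identical copy.

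Epithelial and signalling lists that were not called in A431 held strong single changes. Among basal keratinocyte genes 4 rose, KRT14, ITGA2 and ITGB1 among them, and 7 of 15 fell, also adjusted over the list alone (median -0.10, camera adjusted p = 0.128), KRT15 by -1.88 ± 0.04. Keratinocyte differentiation genes rose in 12 of 29 while KRT13, CNFN, KLK5, KLK6 and CALML5 fell (13 and 5 adjusted over the list alone, median 0.53, or 0.54 over 26 members with groups at 0 set to 3 counts, camera adjusted p = 0.0676), and the transcription factor GRHL3 rose by 1.76 ± 0.11. Immediate early and MAPK feedback genes rose in 10 and fell in 7 of 18, also adjusted over the list alone (median 0.49, camera adjusted p = 0.162). FOSL1 rose by 3.22 ± 0.09 and DUSP6 by 2.48 ± 0.09. In the NOTCH pathway NOTCH1, NOTCH3, JAG1 and HEY1 rose and NOTCH2, JAG2, DLL1, HES1 and NRARP fell of 11, likewise adjusted over the list alone (median -0.04, camera adjusted p = 0.704). YAP targets rose in 6 of 15 while CCN2, AXL and TGFB2 fell, also adjusted over the list alone (median 0.16, camera adjusted p = 0.23). Of 8 WNT targets ZNRF3 and TCF7 rose and RNF43, DKK1 and NOTUM fell, also adjusted over the list alone (median 0.00, mean -0.52, median -0.29 over 6 members with groups at 0 set to 3 counts, camera adjusted p = 0.997). The NOTUM call rested on 28 counts under DMSO and 0 under NEDD8i. It was lost without A431 DMSO replicate 1 (edgeR adjusted p = 0.134), A431 NEDD8i replicate 1 (0.101) or 2 (0.114), or CAL27 DMSO replicate 1 (0.0508).

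No tested list of markers of other cell types was called in A431. Among mesenchymal genes FN1 rose and VIM, SNAI2, TWIST1 and MMP2 fell of 11, also adjusted over the list alone (median -0.51, or -1.04 over 9 members with groups at 0 set to 3 counts, camera adjusted p = 0.132). VIM stood at 0.203 ± 0.0417 CPM and TWIST1 at 0.221 ± 0.0171 CPM under DMSO and 0 counts under NEDD8i. Of 5 fibroblast markers COL1A1 and LUM fell, also adjusted over the list alone (camera adjusted p = 0.513). Their median was -0.53, or -0.88 over 4 members with groups at 0 set to 3 counts. Of 4 endothelial markers CDH5 fell, likewise adjusted over the list alone (camera adjusted p = 0.312). Their median was -0.11, or -0.22 over the 3 members with counts in every group. The COL1A1 call, at -0.53, was lost without A431 DMSO replicate 2 (edgeR adjusted p = 0.103) or A431 NEDD8i replicate 2 (0.179). The leukocyte marker CD14 fell by -2.28 ± 0.24 (-2.87 without A431 NEDD8i replicate 2), also adjusted over the list alone, while LAPTM5 at 0.11 and the melanocyte marker PMEL at -0.05 passed neither way. LAPTM5 stood at 1.85 and passed without A431 DMSO replicate 1 (edgeR adjusted p = 0.00952), and at -0.62 without replicate 2. ITGAM went from 0 counts under DMSO to 12 under NEDD8i, all in replicate 2, and passed when adjusted over the list alone or without A431 NEDD8i replicate 1 (edgeR adjusted p = 0.0229). Genes of the mitochondrial genome fell in 9 of 13 and rose in 0 (13 and 0 adjusted over the list alone, median -0.39, camera adjusted p = 0.055).

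In CAL27, NEDD8i raised NRF2 targets and lowered interferon-stimulated genes, the 2 lists whose calls also held with an estimated correlation. Here 4348 genes were higher and 4943 lower, 1204 and 2309 of them at least 2-fold. SPP1 (ENSG00000118785.15, chromosome 4, 87975667 to 87983529) went from 0.109 ± 0.00369 to 40.4 ± 3.25 CPM, a 366-fold rise (log2 8.52 ± 0.15, edgeR adjusted p = 4.11e-17). AKR1C1 rose 333-fold to 996.6 ± 1.4 CPM. CXCL10, a chemokine induced by interferon, dropped from 16.4 ± 0.284 to 0.1 ± 0.142 CPM, and CCL2, which attracts monocytes, from 34.8 ± 0.647 to 0.245 ± 0.0313 CPM.

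Keratin, protease inhibitor and receptor genes were among the other large rises in CAL27. KRT34, a hair keratin, rose 238-fold, IL1RL1, the receptor of interleukin 33, 204-fold, and the non-coding LINC01127 155-fold. CYP4F3 rose 126-fold, SERPINB2, a plasminogen activator inhibitor, 110-fold to 646.4 ± 41 CPM, the transcription factor CREB5 81.9-fold, ANKRD1, a YAP target, 77.7-fold and HKDC1 64.1-fold. Fitted falls were 153-fold for CXCL10 and 140-fold for CCL2. IDO1, which breaks down tryptophan, fell 96.9-fold, CIITA, the activator of MHC class II genes, 86.2-fold (19.3% of its exonic bases lie in exons of other genes), EGR2 74.6-fold and BBOX1, of carnitine synthesis, 66.2-fold. RCSD1 fell 52.2-fold, S100A7A 46.1-fold, TMEM129, an E3 ligase of the endoplasmic reticulum, 44.1-fold and MMP13 31.3-fold from 184.7 ± 7.58 CPM. Several folds moved by over 1.5 times without 1 library. Without CAL27 DMSO replicate 2 the log2 rises were 8.69 for KRT34 (7.89 with it), 9.17 for IL1RL1 (7.67), 8.41 for LINC01127 (7.28) and 7.76 for CREB5 (6.36). Without replicate 1 they were 7.07 for IL1RL1 and 5.76 for CREB5. Without CAL27 NEDD8i replicate 2 RCSD1 stood at -6.80 (-5.71 with it). All 12 NEDD8i counts of CXCL10 were in that library, so that its log2 change, -7.25 in the fit, was -6.34 without replicate 1 and at most -8.20 without replicate 2, with the floor of 3 counts. Adjusted p for these 20 genes was at most 1.35e-08 by the edgeR quasi-likelihood test, and that of CXCL10 ranged from 9.13e-84 to 0.0718 over 17 alternatives, the highest with DESeq2.

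NRF2 targets rose in 24 of 27 members in CAL27 and PIR fell, with the same counts adjusted over the list alone (median 1.73, camera adjusted p = 1.7e-13, and adjusted p = 0.0359 with an estimated correlation). AKR1C2 rose by 5.54 ± 0.09, SLC7A11 by 4.34 ± 0.07 and TXNRD1 by 3.32 ± 0.04. HIF targets rose in 19 of 23 while CA12, EGLN3 and PFKFB4 fell, also adjusted over the list alone (median 0.66, camera adjusted p = 1.84e-05, adjusted p = 0.166 with an estimated correlation). BNIP3 rose by 2.32 ± 0.05 and BNIP3L by 1.90 ± 0.07. Integrated stress response genes rose in 18 of 24 while DDIT4, SLC7A5, CEBPB and NUPR1 fell, likewise adjusted over the list alone (median 0.61, camera adjusted p = 8.22e-05, adjusted p = 0.187 with an estimated correlation). CHAC1 rose by 3.22 ± 0.09 and PPP1R15A by 2.63 ± 0.08. YAP targets rose in 10 of 15 while CCN2, PTPN14, ARHGEF17 and FJX1 fell, also adjusted over the list alone (median 0.58, camera adjusted p = 0.012, adjusted p = 0.25 with an estimated correlation). AMOTL2 rose by 1.83 ± 0.05 and LATS2 by 1.57 ± 0.09.

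G2/M genes fell in 25 of 28 members in CAL27 and rose in 0, also adjusted over the list alone (median -1.18, camera adjusted p = 4.68e-10, adjusted p = 0.166 with an estimated correlation). KIF20A stood at -2.83 ± 0.08, PLK1 at -2.64 ± 0.07, AURKA at -2.03 ± 0.06 and CCNB1 at -1.84 ± 0.06. G1/S genes rose in 19 of 25 while PRIM1 and UNG fell, likewise adjusted over the list alone (median 0.53, camera adjusted p = 6.41e-06, adjusted p = 0.0666 with an estimated correlation). CDC25A rose by 1.71 ± 0.08, CCNE2 by 1.61 ± 0.10 and FEN1 by 1.10 ± 0.05. Replication-dependent histones fell in 7 of 14 and rose in 0, also adjusted over the list alone (median -1.57, camera adjusted p = 0.00515, adjusted p = 0.178 with an estimated correlation). Replication licensing genes rose in 10 and fell in 7 of 21 (10 and 8 adjusted over the list alone, median 0.14, camera adjusted p = 0.332), CDC6 by 1.55 ± 0.05 and ORC6 by 1.45 ± 0.07. Targets of p53 rose in 10 and fell in 8 of 26 (10 and 10 adjusted over the list alone), with a median of -0.04, a mean of 0.16 and a camera adjusted p of 0.463, and CDKN1A rose by 2.87 ± 0.06.

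Interferon-stimulated genes fell in 23 of 26 members in CAL27 and rose in 0, also adjusted over the list alone (median -2.08, camera adjusted p = 4.68e-10, and adjusted p = 0.0359 with an estimated correlation). IFIT3 stood at -3.19 ± 0.06, OAS2 at -2.64 ± 0.07 and MX1 at -1.76 ± 0.06. Antigen presentation genes fell in 10 of 14 and HLA-E rose (12 and 1 adjusted over the list alone, median -0.69, camera adjusted p = 0.00102, adjusted p = 0.178 with an estimated correlation). PSMB9 stood at -2.68 ± 0.07 and PSMB10 at -2.51 ± 0.12. NF-kB targets fell in 17 of 25 while TNFAIP3, CXCL8, CSF2 and PTGS2 rose, also adjusted over the list alone (median -1.13 with or without groups at 0 set to 3 counts, camera adjusted p = 0.000577, adjusted p = 0.178 with an estimated correlation). TNFAIP2 fell by -3.24 ± 0.05, CXCL1 by -3.14 ± 0.10 and NFKBIA, the inhibitor of NF-kB, by -3.12 ± 0.08. NOTCH pathway genes fell in 8 of 11 and HES4 rose, likewise adjusted over the list alone (median -1.19, camera adjusted p = 0.00262, adjusted p = 0.187 with an estimated correlation), HES1 by -3.31 ± 0.09, JAG2 by -2.91 ± 0.08 and NOTCH1 by -1.99 ± 0.07.

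Cholesterol synthesis genes fell in 16 of 20 members in CAL27 while FDPS and CYP51A1 rose, also adjusted over the list alone (median -0.53, camera adjusted p = 0.000225, adjusted p = 0.365 with an estimated correlation). LSS fell by -1.84 ± 0.07 and INSIG1 by -1.28 ± 0.06. Proteasome subunits rose in 23 of 31 and PSMD7 fell (24 and 1 adjusted over the list alone, median 0.39, camera adjusted p = 2.32e-06, adjusted p = 0.166 with an estimated correlation). PSMD2 rose by 1.11 ± 0.04. Ribosomal protein genes rose in 27 of 51 while RPL3, RPL10A, RPL37 and RPS9 fell (31 and 4 adjusted over the list alone, median 0.13, camera adjusted p = 0.00262, adjusted p = 0.365 with an estimated correlation). Lists of the modifier pathways were also called higher, each without holding at an estimated correlation. Neddylation enzymes rose in 7 of 13 and SENP8 fell (10 and 1 adjusted over the list alone, median 0.35, camera adjusted p = 0.0154, adjusted p = 0.187 with an estimated correlation). DCUN1D3 rose by 1.43 ± 0.15. Cullin-RING ligase components rose in 13 of 30 while CUL7, CUL9, VHL, CAND1 and KLHL12 fell (15 and 5 adjusted over the list alone, median 0.23, camera adjusted p = 0.0105, adjusted p = 0.166 with an estimated correlation). KLHL21 rose by 1.76 ± 0.06 and DTL by 1.05 ± 0.06. Subunits of the COP9 signalosome, which removes NEDD8 from cullins, rose in 9 of 10 and COPS7A fell, also adjusted over the list alone (median 0.35, camera adjusted p = 0.00889, adjusted p = 0.178 with an estimated correlation). The SUMO pathway rose in 10 of 17 and RANBP2 fell, likewise adjusted over the list alone (median 0.30, camera adjusted p = 0.0217, adjusted p = 0.211 with an estimated correlation). SENP5 rose by 0.88 ± 0.07 and SUMO2 by 0.49 ± 0.04. Of these 18 called lists, 11 higher and 7 lower, NRF2 targets and interferon-stimulated genes held with an estimated correlation.

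Lists that were not called in CAL27 also held strong single changes. Among basal keratinocyte genes 7 rose and 7 fell of 15, also adjusted over the list alone (median 0.10 but mean -0.31, camera adjusted p = 0.954). KRT15 stood at -3.32 ± 0.04, LAMB3 at 1.45 ± 0.04 and TP63, the master regulator of stratified epithelium, at -2.18 ± 0.06. Keratinocyte differentiation genes rose in 10 and fell in 9 of 29 (10 and 10 adjusted over the list alone, median 0.51, camera adjusted p = 0.422). GRHL3 rose by 4.30 ± 0.15 and KLF4 fell by -1.23 ± 0.07. Stress keratins and alarmins rose in 7 and fell in 6 of 15, also adjusted over the list alone (median 0.06, camera adjusted p = 0.323). PI3 rose by 1.99 ± 0.09. In the EGFR list AREG, EREG, HBEGF and TGFA rose and EGFR, ERBB2, ERBB3, BTC and NRG1 fell of 10, also adjusted over the list alone (median 0.33, camera adjusted p = 0.642). Immediate early genes rose in 8 and fell in 9 of 18, also adjusted over the list alone (median 0.07 but mean -0.38, camera adjusted p = 0.968). DUSP6 rose by 2.90 ± 0.08 and FOS fell by -4.24 ± 0.09. Among matrix proteases 4 rose, MMP14, PLAUR and SERPINE2 among them, and MMP1, MMP10, MMP13, PLAU and PLAT fell of 11 (4 and 6 adjusted over the list alone), with a median of -0.18 and a mean of -0.40 while camera ranked the list upward (camera adjusted p = 0.83). Of 8 WNT targets RNF43, TCF7 and DKK1 rose and 0 fell, also adjusted over the list alone (median 0.42, camera adjusted p = 0.218). The RNF43 call was lost without CAL27 DMSO replicate 1 (edgeR adjusted p = 0.0723).

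BCL2 family genes rose in 8 of 14 in CAL27 while BID and BMF fell (8 and 3 adjusted over the list alone, median 0.29, camera adjusted p = 0.0766). BCL2L1 rose by 2.05 ± 0.06 and PMAIP1 by 1.66 ± 0.07. Among endoplasmic reticulum chaperones DNAJB9, XBP1, SDF2L1, EDEM1 and DNAJB11 rose and 8 of 17 fell, also adjusted over the list alone (median -0.08, camera adjusted p = 0.505). Among heat shock genes DNAJA1, DNAJB1, BAG3, HSP90AB1 and HSPA4L rose and HSPA8 and HSPB1 fell of 13, likewise adjusted over the list alone (median 0.06, camera adjusted p = 0.387). In ribosome biogenesis FBL, RRP12, PES1, LYAR and NOLC1 rose and 7 of 19 fell (6 and 7 adjusted over the list alone, median 0.03 but mean -0.05, camera adjusted p = 0.965). Autophagy and lysosome genes rose in 8 and fell in 7 of 18, also adjusted over the list alone (median 0.05, camera adjusted p = 0.577). MAP1LC3B rose by 1.67 ± 0.05 and TFEB fell by -2.71 ± 0.13. Among mesenchymal genes SNAI1 and TAGLN rose and CDH2, SNAI2, MMP2 and SPARC fell of 11 (3 and 4 adjusted over the list alone, median -0.33, camera adjusted p = 0.32), SPARC by -2.43 ± 0.05.

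No tested list of markers of other cell types was called in CAL27 either. Of 5 fibroblast markers COL1A1 and COL1A2 fell, also adjusted over the list alone (camera adjusted p = 0.155). Their median was -2.25, or -1.74 over the 4 members with more than 3 counts in a CAL27 group. The fitted median was -0.58 without CAL27 DMSO replicate 2 and -1.44 without CAL27 NEDD8i replicate 1. Of 4 endothelial markers CDH5 rose, likewise adjusted over the list alone (median 0.19, camera adjusted p = 0.709). The median was 0.81 to 0.83 without any 1 of the 4 A431 libraries. Fits without 1 library tested 20232 to 20723 genes against 18738, so the members tested in a list can differ. These changes in median therefore need not come from the CAL27 values. The leukocyte markers CD14, at -3.36 ± 0.23, LAPTM5, at -1.90 ± 0.40, and ITGAM fell, also adjusted over the list alone, and the melanocyte marker PMEL, at 0.42, passed neither way. The ITGAM call rested on 70 counts under DMSO and 2 under NEDD8i and was lost in 3 of 15 alternatives, without CAL27 DMSO replicate 1 (edgeR adjusted p = 0.0551) or 2 (0.239) or CAL27 NEDD8i replicate 2 (0.148), over a range from 0.00207 to 0.239. Genes of the mitochondrial genome fell in 10 of 13 and rose in 0, also adjusted over the list alone (median -0.42, camera adjusted p = 0.107).

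**Figure D1:**
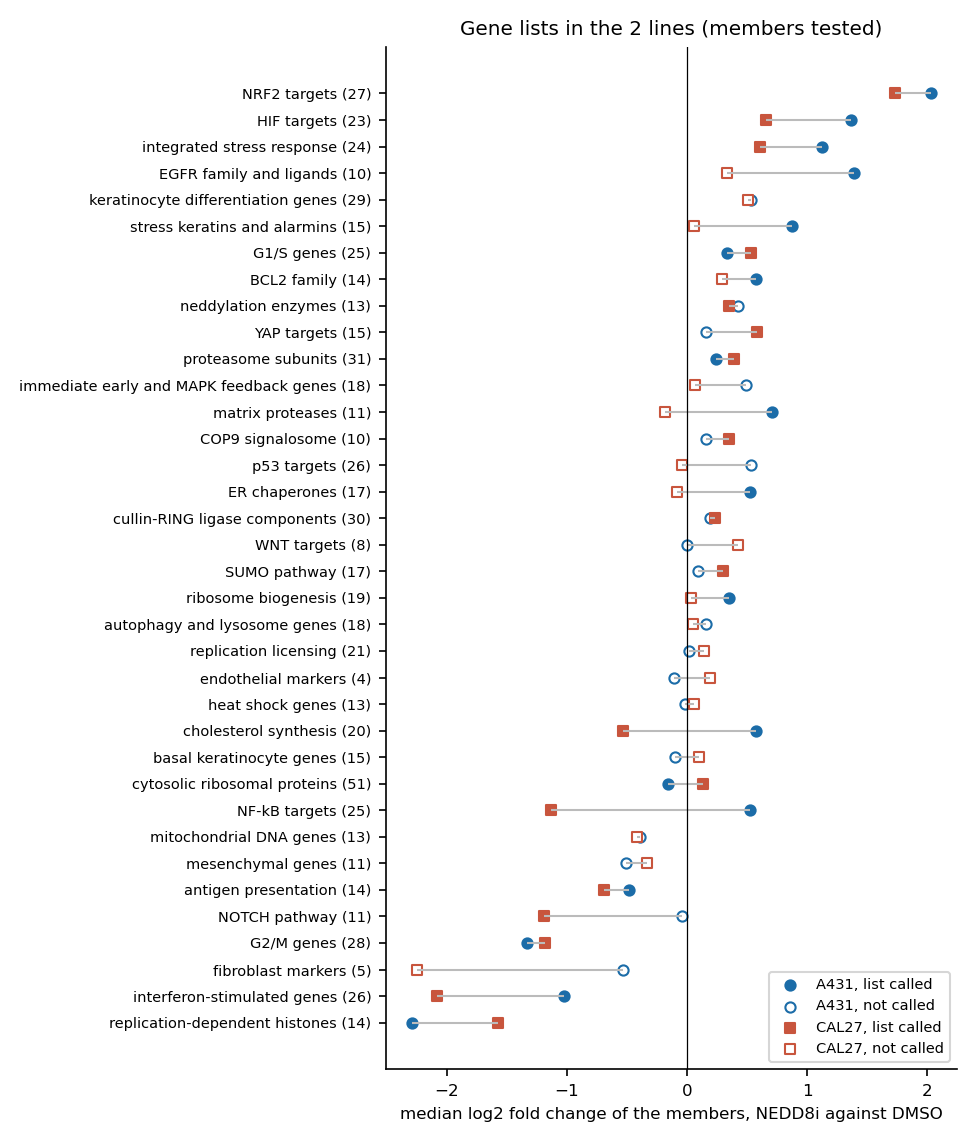
Median log2 fold change (horizontal axis, NEDD8i against DMSO) of the members of 36 of the 37 tested gene lists, with A431 as circles and CAL27 as squares, filled where camera called the list at adjusted p under 0.05, and the number of members tested in brackets. NRF2 targets stand farthest right at 2.03 and 1.73, interferon-stimulated genes at -1.02 and -2.08, and cholesterol synthesis lies on opposite sides of 0 at 0.57 and -0.53.

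The lines shared a large part of their response. A total of 2488 genes rose in both, where independent lists of these sizes would share 980.1. Likewise 2405 fell in both, where 1042 would be shared. Odds ratios were 9.75 and 7.51 (Fisher's exact test, one-sided, p at most 1e-300 for each). That test takes genes as independent, which they are not, so its p does not measure how well the response replicates. Opposite calls were fewer than independent lists would give: 616 genes rose in A431 and fell in CAL27 against 1114, and 319 did the reverse against 916.8. Across the tested genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.37 and a Spearman rank correlation of 0.43. Among the 5 strongest shared rises were HKDC1 (6.18 in A431, or 7.05 without A431 DMSO replicate 2, and a 64.1-fold rise in CAL27), SPP1 (5.67 and 8.52), CYP4F3 (5.64 and 6.98) and MAP2 (4.96 and 4.73). The 5 strongest shared falls were CYP1B1 (-4.00 and -4.31), OLFML2A, an olfactomedin-like protein (-3.61 and -3.73), MMP13 (-3.51 and -4.97), FBXO32, a substrate receptor of a cullin-RING ligase (-3.42 and -4.66), and TNFSF10, which encodes the death ligand TRAIL (-3.20 and -4.08). TNFSF10 went from 209.7 ± 2.91 to 22.7 ± 0.0906 CPM in A431 and from 218 ± 6.31 to 12.9 ± 0.151 CPM in CAL27.

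**Figure D2:**
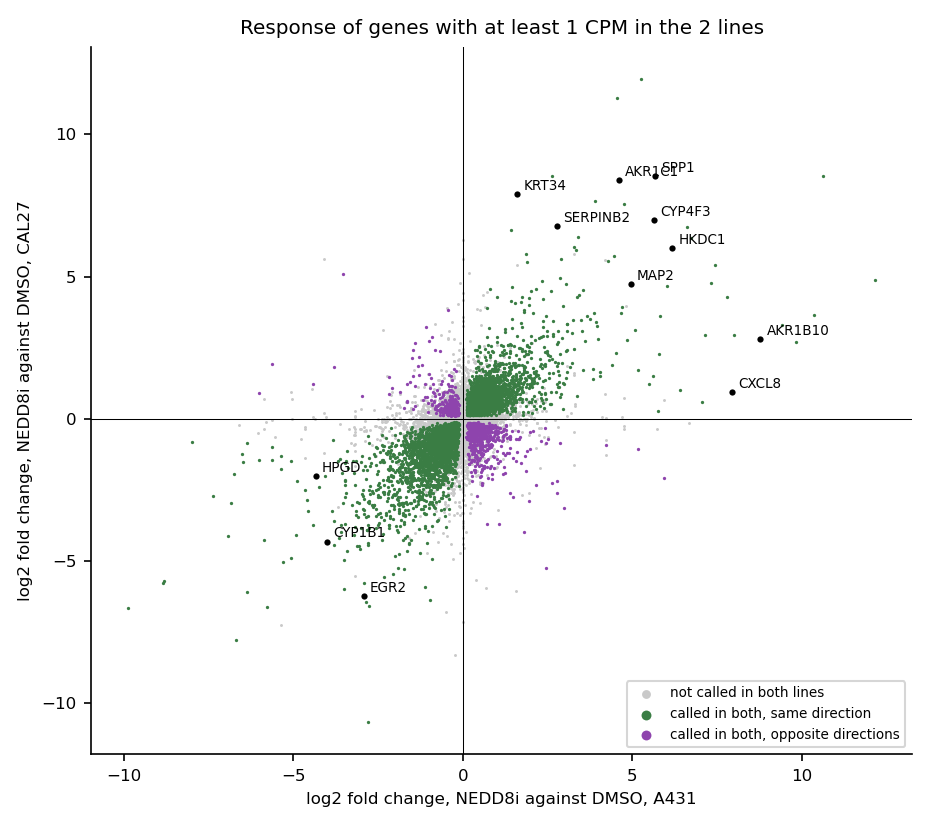
Log2 fold change, NEDD8i against DMSO, in A431 (horizontal axis) and CAL27 (vertical axis) of the 12837 tested genes with a mean of at least 1 CPM over the 4 groups, each point a gene. Of these, 4728 were called in both lines with one direction (green) and 926 with opposite directions (purple), and AKR1B10 and CXCL8 lie far to the right with smaller rises in CAL27.

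**Figure D3:**
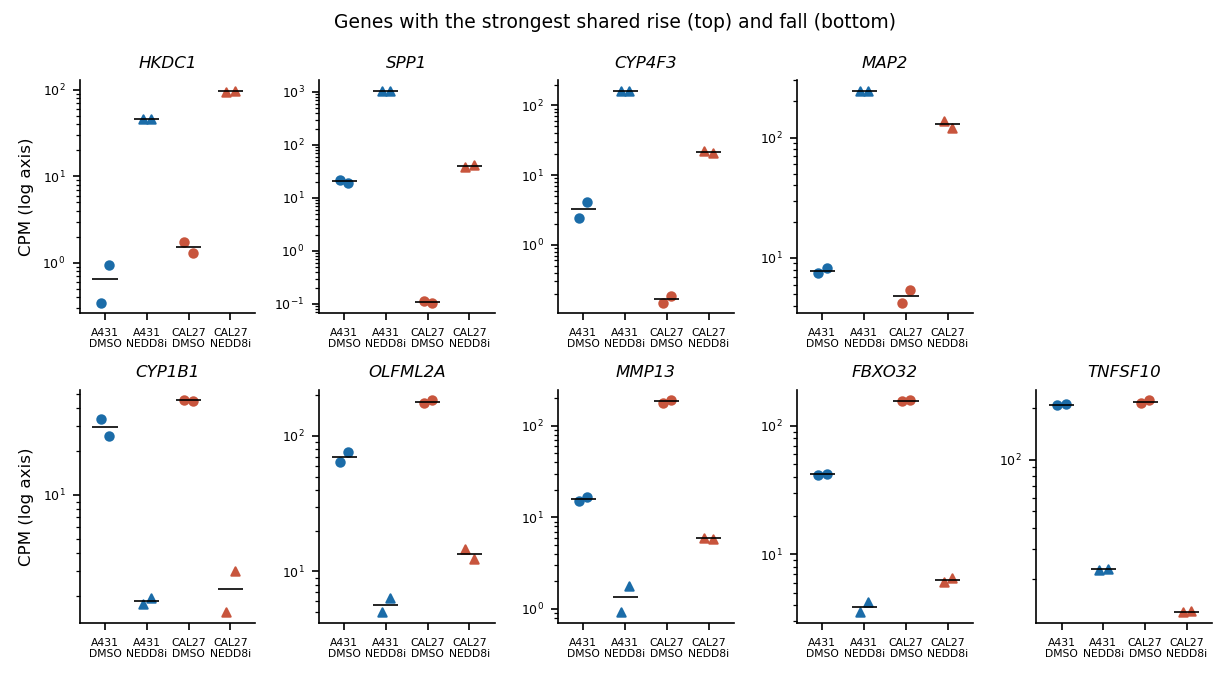
CPM on a log axis of 4 of the 5 genes with the strongest shared rise (top row) and the 5 with the strongest shared fall (bottom row) in each library, with circles for DMSO, triangles for NEDD8i, blue for A431, red for CAL27 and a bar at each group's mean (n = 2). Both NEDD8i libraries lie apart from both DMSO libraries of their line in every panel, as for TNFSF10 at 22.7 against 209.7 CPM in A431.

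NF-kB targets and cholesterol synthesis genes had the smallest camera p of the lists where the response to NEDD8i differed between the lines. In the test of the difference, CAL27 response minus A431 response, 6369 genes passed, 2658 with a higher and 3711 with a lower value in CAL27. Of these, 935 were called in both lines with opposite signs, 2137 in both with one sign, 1258 in A431 alone and 1914 in CAL27 alone. NF-kB targets were lower in CAL27 in 17 of 25 members and only TRAF1 was higher (18 and 2 adjusted over the list alone). The median difference was -2.25, or -1.81 over the 21 members with counts in every group. The camera adjusted p was 3.46e-09, and adjusted p = 0.178 with an estimated correlation. CXCL8 differed by -7.00 ± 0.19 (-8.18 without A431 DMSO replicate 1 and -6.40 without replicate 2), CXCL1 by -6.12 ± 0.22, IL1B by -3.69 ± 0.12 and IL1A by -3.22 ± 0.12. CXCL8 already stood at 157.7 ± 14.8 CPM in CAL27 under DMSO. CXCL1, CXCL2 and CXCL3 share near-identical sequence. Cholesterol synthesis genes were lower in 19 of 20 members and higher in 0, also adjusted over the list alone (median difference -0.95, camera adjusted p = 3.46e-09, adjusted p = 0.346 with an estimated correlation). MVD stood at -2.43 ± 0.12 and SQLE, squalene epoxidase, at -1.50 ± 0.07.

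**Figure D4:**
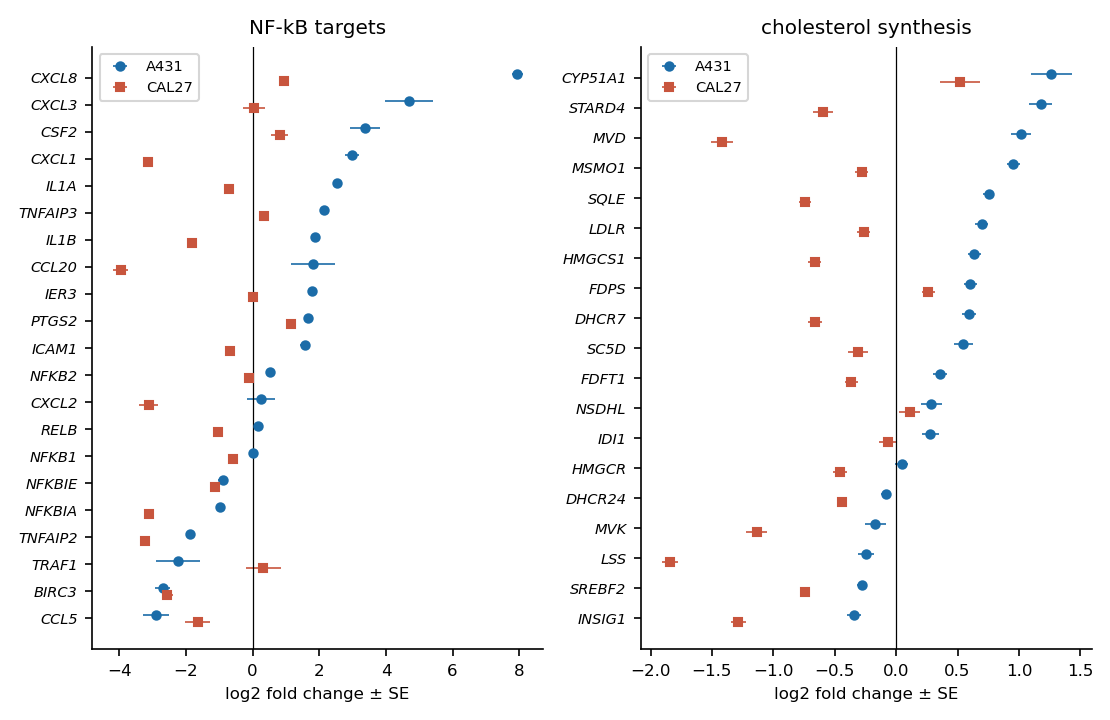
Log2 fold change ± approximate SE (horizontal axis, NEDD8i against DMSO), with A431 as blue circles and CAL27 as red squares. The 21 NF-kB targets with counts in all 4 groups are on the left, and 19 of the 20 cholesterol synthesis genes on the right. CXCL1 had a difference of -6.12 between the lines, and in the right panel 13 genes rose in A431 and 15 fell in CAL27.

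The other lists called for the difference were lower in CAL27, except ribosomal proteins. HIF targets were lower in 15 of 23 members while BNIP3L and PFKFB3 were higher (16 and 2 adjusted over the list alone, median -0.76, camera adjusted p = 1.39e-05, adjusted p = 0.3 with an estimated correlation). BNIP3 stood at -2.20 ± 0.08. Interferon-stimulated genes were lower in 18 of 26 while IFI6, IFI27, STAT2, IRF7 and HERC5 were higher, also adjusted over the list alone (median -0.88, camera adjusted p = 0.000235, adjusted p = 0.178 with an estimated correlation). CMPK2 stood at -2.81 ± 0.17. NOTCH pathway genes were lower in 6 of 11 while HES4 was higher (7 and 1 adjusted over the list alone, median -1.42, camera adjusted p = 0.0117, adjusted p = 0.408 with an estimated correlation). NOTCH3 stood at -2.35 ± 0.08 and NOTCH1 at -2.26 ± 0.09. EGFR family genes were lower in 7 of 10 while TGFA was higher, also adjusted over the list alone (median -0.75, camera adjusted p = 0.00961, adjusted p = 0.3 with an estimated correlation). EREG stood at -1.63 ± 0.07 and EGFR at -0.90 ± 0.05. Endoplasmic reticulum chaperones were lower in 11 of 17 and higher in 0, also adjusted over the list alone (median -0.50, camera adjusted p = 0.00166, adjusted p = 0.408 with an estimated correlation). Ribosome biogenesis genes were lower in 13 of 19 while FBL was higher (15 and 2 adjusted over the list alone, median -0.33, camera adjusted p = 0.00596, adjusted p = 0.408 with an estimated correlation). Immediate early genes were lower in 9 of 18 while FOSL2 and DUSP6 were higher (10 and 2 adjusted over the list alone, median -0.67, camera adjusted p = 0.0211, adjusted p = 0.571 with an estimated correlation and 0.0571 over genes with at least 1 CPM in a group, range 0.00212 to 0.571 over 16 alternatives). MYC stood at -2.84 ± 0.09 and FOS at -2.70 ± 0.11. Ribosomal protein genes were higher in CAL27 in 40 of 51 members and RPL10A was lower (43 and 1 adjusted over the list alone, median 0.30, camera adjusted p = 6.78e-09, adjusted p = 0.335 with an estimated correlation). By camera with an estimated correlation 0 of the 10 lists held (5 of the 37 lists had an unadjusted p under 0.05), while fry, which does not compare a list with other genes, called 27. The other 27 lists tested were not called, the lowest camera adjusted p being 0.0523, for G1/S genes. Among these the signs of median, mean and test differed for neddylation enzymes (median -0.07, mean 0.02), basal keratinocyte genes (0.23 and -0.02), BCL2 family genes (0.08 and -0.21) and mitochondrial DNA genes (-0.06 and -0.03), each of which camera ranked upward.

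Single genes with the largest fitted differences included several that one line hardly expressed. For C16orf54, F2RL2, IGFL1, FLRT2 and EPB41L2 a group had 0 counts, so their rank rests on values that are not folds. Set against the floor, their differences were at most -4.52, -3.67 and -3.54, and at least 3.48 and 1.93, in that order. CXCL8 at -7.00 and AKR1B10 at -5.97, with counts in every group, lay farther from 0 than these bounds. ADAMTS6, a secreted protease, rose from 3.7 ± 0.457 to 126.2 ± 10.9 CPM in CAL27, while A431 had 28 counts under DMSO and 2 under NEDD8i (ratio 0.0774, 95% exact interval 0.00894 to 0.307). KRT34 rose by 7.89 ± 0.27 in CAL27 (8.69 without CAL27 DMSO replicate 2) and by 1.60 ± 0.50 in A431, from 19 to 54 counts. The A431 call was lost in 5 of 17 alternatives, without A431 DMSO replicate 1 (edgeR adjusted p = 0.0887) or A431 NEDD8i replicate 2 (0.496, with a log2 change of 0.59), in the 4 A431 libraries alone (0.163). It was also lost with DESeq2 (0.0753) and with voom (0.173), over a range from 0.000227 to 0.496. SEMA6D fell by -3.79 ± 0.27 in A431 and rose by 1.81 ± 0.48 in CAL27, from 10 to 34 counts. That rise was lost without CAL27 DMSO replicate 2 (edgeR adjusted p = 0.0633), in the 4 CAL27 libraries alone (0.114) and with voom (0.101), over a range from 0.00343 to 0.114. FLRT2, an adhesion protein, had 0 counts in A431 under NEDD8i against 62 under DMSO and was at least 19.4-fold lower there. EPB41L2 passed on 12 A431 counts, all in DMSO replicate 2, and did not pass without that library (edgeR adjusted p = 1 in A431, over a range from 0.000116 to 1). In the other direction, ZNF469 rose by 2.45 ± 0.25 in A431 and fell by -5.24 ± 0.52 in CAL27 (-4.36 without CAL27 NEDD8i replicate 1, and at most -4.65 with the floor of 3 counts without replicate 2, which held all 4 counts). BBOX1 fell by -6.05 in CAL27 against a log2 change of 1.57 in A431 that did not pass, a difference of -7.62 ± 0.88. The A431 change passed without A431 DMSO replicate 1, which held all 8 DMSO counts (at least 1.96 with the floor of 3 counts, edgeR adjusted p = 0.00132), or A431 NEDD8i replicate 2 (2.05, 0.0461). It also passed with DESeq2 (0.0478) and with the replicate number as a block (0.0327). It was 0.65 without A431 DMSO replicate 2 (0.47) and 0.98 without A431 NEDD8i replicate 1 (0.445). The difference was at most -7.99 without A431 DMSO replicate 1, -6.69 without replicate 2 and -7.01 without A431 NEDD8i replicate 1. C16orf54 had 0 counts in CAL27 under NEDD8i against 86 and was at least 27-fold lower. F2RL2 rose by 4.89 ± 0.27 in CAL27, and IGFL1, an insulin growth factor-like protein, was at least 74.8-fold higher in A431 and rose by 2.69 ± 0.16 in CAL27. Exons of other genes cover 12.2% of the exonic bases of IGFL1.

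Under DMSO the lines differed in 11045 genes, 5602 higher in CAL27 and 5443 higher in A431. SPARC, a matrix glycoprotein, stood at 671.9 ± 1.16 CPM in CAL27 with 0 counts in A431, at least 24430-fold higher with the floor of 3 counts over the group. OLFM4 (at least 8685-fold), the chemokine CX3CL1 (at least 5274-fold), MAGEA6 (at least 4114-fold) and the mannosidase MAN1A1 (at least 2724-fold) were likewise at 0 in A431. MAGEA6 shares near-identical sequence with other MAGEA genes. The 5 largest in the other direction had 0 counts in CAL27: UGT1A10 (at least 4829-fold), SLC20A2, a phosphate transporter (at least 4029-fold), MPPED2 (at least 3208-fold), PEG10 (at least 1652-fold) and BPIFB1 (at least 1351-fold). Exons of neighbouring UGT1A genes cover 70.6% of the exonic bases of UGT1A10. Line, culture medium and any processing batch cannot be told apart in this comparison.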

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

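In this part the tests of scaling and of single libraries were chosen after the result was seen. Groups of 2 libraries are too small to test for a deviating sample, so every result here is a response that differed between the lines by the test of the difference, given as CAL27 minus A431 on the log2 scale.

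Of the gene lists, 10 differed, and 0 of them held with an estimated correlation (camera adjusted p from 0.178 to 0.571). Median differences were -2.25 for NF-kB targets, -1.42 for the NOTCH pathway, -0.95 for cholesterol synthesis, -0.88 for interferon-stimulated genes, -0.76 for HIF targets, -0.75 for the EGFR family and its ligands, -0.67 for immediate early and MAPK feedback genes, -0.50 for endoplasmic reticulum chaperones, -0.33 for ribosome biogenesis and 0.30 for cytosolic ribosomal proteins.

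Of 48 single genes considered, 29 differed, 15 with a lower and 14 with a higher response in CAL27. The lower ones were ZNF469 at -7.69, BBOX1 at -7.62, CXCL8 at -7.00, AKR1B10 at -5.97, CIITA at -3.58, TMEM129 at -3.40 and EGR2 at -3.30. Also lower, PNLIPRP3 differed by -2.23, MMP13 by -1.46, FBXO32 by -1.23, TNFSF10 by -0.88 and NAE1 by -0.71. With groups at 0 set to 3 counts, the difference was at most -4.52 for C16orf54, -3.67 for F2RL2 and -3.54 for IGFL1. It was at least 1.93 for EPB41L2 and 3.48 for FLRT2. The higher ones were NEDD8 at 0.30, CYP4F3 at 1.34, PSCA at 2.04, HPGD at 2.33, SPP1 at 2.84, AKR1C1 at 3.77, IL1RL1 at 3.77 and SERPINB2 at 4.01. FAXDC2 differed by 4.08, SEMA6D by 5.60, KRT34 by 6.29 and ADAMTS6 by 8.65, the last resting on 2 counts in A431 under NEDD8i. The NEDD8 difference (edgeR adjusted p = 0.0198) was lost in 4 of 16 alternatives, without A431 NEDD8i replicate 1 (0.068) or 2 (0.0575), CAL27 DMSO replicate 1 (0.0654) or CAL27 NEDD8i replicate 1 (0.0524), over a range from 0.0046 to 0.068. CYP4F3 was lost in 3 of 16, with voom (0.205) and without CAL27 DMSO replicate 1 (0.0957) or 2 (0.0755), over a range from 3.42e-05 to 0.205. EPB41L2 was lost in 8 of 16, over a range from 0.000181 to 1, and has no fold without A431 DMSO replicate 2, which held its 12 A431 counts. PNLIPRP3 was lost in 2 of 16, with voom (0.0603) and without CAL27 DMSO replicate 2 (0.14, with a difference of -1.49). Other differences moved by over 1.5 times without 1 library. Without A431 DMSO replicate 1 CXCL8 stood at -8.18, and without replicate 2 CXCL8 stood at -6.40 and BBOX1 at -6.69. Without A431 NEDD8i replicate 1 BBOX1 stood at -7.01 and ADAMTS6 at 7.86, and without replicate 2 KRT34 stood at 7.30. Without CAL27 DMSO replicate 1 IL1RL1 stood at 3.17 and HPGD at 2.91, and without replicate 2 IL1RL1 stood at 5.27 and KRT34 at 7.09. Without CAL27 NEDD8i replicate 1 ZNF469 stood at -6.82 and FAXDC2 at 3.10, and without replicate 2 FAXDC2 stood at 4.68. Where leaving out a library brought a group to 0, with the floor of 3 counts, BBOX1 was at most -7.99 (without A431 DMSO replicate 1), ZNF469 at most -7.11 (without CAL27 NEDD8i replicate 2) and ADAMTS6 at least 7.09 (without A431 NEDD8i replicate 2).

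NF-kB targets moved apart in the lines, with a fitted median difference of -2.25 over 25 members and quartiles of -4.64 and -0.64. The list call was lost with an estimated correlation (camera adjusted p = 0.178). Of these members, 4 had a group at 0 counts, so their fitted differences are not folds. Over the 21 members with counts in every group the median difference was -1.81. Of these, 12 rose and 6 fell in A431, and 4 rose and 13 fell in CAL27. Not all moved in opposite directions. NFKBIA (-0.99 in A431 and -3.12 in CAL27), NFKBIE (-0.90 and -1.13), TNFAIP2 (-1.88 and -3.24), BIRC3 (-2.69 and -2.55) and CCL5 (-2.89 and -1.65) fell in both lines. A shift in scaling would move all genes of like level alike. In 10000 random lists of 25 members matched on mean level, the middle 99% of medians ran only from -0.56 to 0.36. TMM scaling centres most genes (median difference over all tested genes -0.0376), so the range would lie near 0 under a wrong scaling too. It shows that the list moved apart from genes of like level, and cannot decide whether the scaling was right. The median of -2.25 lay at the 0.01 percentile, the smallest they can give. That rank adds no support, because the list had one of the smallest camera p, and camera also compares a list with other genes. In the fits that each leave out 1 of the 8 libraries, the fitted median came no nearer to 0 than -2.13. This argues against a single deviating library, though members with a group at 0 were kept in these medians. Without CXCL1, CXCL2, CXCL3 and members with over 10% shared exonic bases, 19 members were left, with a median of -1.81. This argues against reads shared between near-identical or overlapping genes, though the 19 were not limited to members with counts in every group. A biological difference between the lines may remain, as a hypothesis, and line, medium and any batch that goes with the line cannot be told apart and were not tested.

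Cholesterol synthesis genes also moved apart, with a median difference of -0.95 and quartiles of -1.35 and -0.49, and this list call was lost with an estimated correlation as well (camera adjusted p = 0.346). In 10000 matched random lists the middle 99% of medians ran only from -0.38 to 0.27. This list too moved apart from genes of like level. For the reason given above, that range cannot decide whether the scaling was right. The median of -0.95 lay at the 0.01 percentile, again the smallest they can give, a rank that adds no support for the same reason. Without each of the 8 libraries in turn the median difference came no nearer to 0 than -0.89, which argues against a single library. A trend with gene length and level, fitted on all tested genes, explained 1.2% of the deviance and left a median of -0.83 when removed. A difference between the lines may remain here too, untested against medium and batch.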

How the results depend on the processing

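Of the alternatives in this part, the fit with counts divided by 2 was chosen after seeing the data. All counts of called genes stayed within 1.5 times those reported under every alternative run. Over the genes named or listed, 9457 results kept their side of the threshold, 86 lost and 44 gained a call and 2 reversed. Over the lists 1702 kept their side, 51 lost and 84 gained a call and 1 reversed. A change of sign was counted as a reversal only where a fit called the result. Results called in neither fit may therefore have changed sign. DESeq2 called 7987 genes in A431, 9008 in CAL27, 6212 for the difference and 10732 under DMSO. With counts divided by 2 the calls were 8422, 9633, 6541 and 11146, of which 7980, 9088, 6214 and 10637 were shared with those reported. Upper-quartile factors gave 3701 higher and 4550 lower genes in A431 and 3184 higher and 3239 lower for the difference. DESeq2 and voom were not run for lists, and a fit of only the libraries compared was not run for the difference, which needs all 8.

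The numbers of called lists depended on the test. With an estimated correlation camera called 1 list in A431, 2 in CAL27 and 0 for the difference (12, 10 and 5 with an unadjusted p under 0.05), and fry called 34, 32 and 27. The cause was not tested, though fry does not compare a list with other genes. In A431 the estimated correlation was -0.018 for G1/S genes, -0.00868 for interferon-stimulated genes and -0.0165 for the EGFR list, below the preset 0.01. Their calls were lost nonetheless, so for these lists the loss did not come from more correlation among members. Other lists lay above the preset, such as cholesterol synthesis at 0.358. WNT targets in A431, with a median of 0.00, were ranked down by camera (adjusted p = 0.997) and up by fry (adjusted p = 0.0034).

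Leaving out each library in turn, where the lone library of its group is assumed to vary like the others, gave 6864 to 8354 called genes in A431, 7766 to 9591 in CAL27, 5240 to 6023 for the difference, 9438 to 11131 under DMSO and 4298 to 4678 in both lines. Called lists ranged from 18 to 21, 18 to 20 and 10 to 11. These fits tested 20232 to 20723 genes, against 18738 with all libraries, so gene counts and list medians are not over the same genes. EPB41L2 had all its 12 A431 counts in DMSO replicate 2. Its fitted values, which are set against 0 counts and are not folds, ranged from -6.69 to 0.00 in A431 and from -0.02 to 6.67 for the difference, with 0.00 and -0.02 without that library. A group with 0 counts was set to a floor of 3 counts over its 2 libraries. In a single library 3 counts would be 0.048 to 0.0612 CPM. That floor takes counts as independent. Since each mate of a pair counted once, counting error allows more than 3 counts.

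Deviations from the group means of replicates with the same number correlated with 0.10 in A431, -0.01 in CAL27 and -0.00 between the lines under DMSO, which does not exclude a shared batch or day. A fit with the replicate number as a block gave 8096 genes in A431, 9217 in CAL27, 6416 for the difference and 10765 under DMSO, with 7922, 9036, 6189 and 10715 shared with those reported. The block gave 19, 19 and 10 called lists, and NF-kB targets in A431 had a camera adjusted p of 0.0507 with it.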

Other observations

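The test of shared exons in this part was chosen after the result was seen, and the genes named here were chosen after their values were seen. Some genes had 0 counts in all 4 libraries of a line while the other line held at least 5 CPM on average, 40 protein-coding genes in A431 and 16 in CAL27. Absent in A431 were the matrix protein SPARC (398.4 CPM in CAL27 over its 4 libraries), OLFM4 (125.1), CX3CL1 (78.5), MAN1A1 (66.4), SPART (46.5) and CDH2, which encodes N-cadherin (29.5). Absent in CAL27 were SLC20A2 (267.4 CPM in A431), MPPED2 (48.1), PEG10 (27.6), BPIFB1 (26) and SMIM19 (14.6). SLC20A2 (chromosome 8, 42416475 to 42541926 on GRCh38) and SMIM19 (chromosome 8, 42541155 to 42555195) are neighbours whose ends overlap. Also among the 16 genes at 0 in CAL27 were ZNF260 (13.3 CPM in A431), ZNF649 (9.6), ZNF160 (8.66), ZNF611 (6.28) and ZNF567 (5.14).

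PSMA2, a proteasome subunit, NUSAP1, a mitotic protein, ASNS, asparagine synthetase, and the antiviral genes RIGI and IRF9 had almost no counts, with means of 0.349, 0.143, 0.473, 0.0755 and 0.0574 CPM. A candidate explanation is that exons shared with another annotated gene removed their reads from the counts. Exons of other genes cover 94.7% of the exonic bases of PSMA2, 92.2% of NUSAP1, 82.4% of ASNS, 87.7% of RIGI and 86.3% of IRF9. Of 556 protein-coding genes with at least 90% of exonic bases shared, 98.9% had under 1 CPM, against 43.4% of 12347 genes with none shared. ASNS, RIGI and IRF9 lie below that 90% limit. The overlap was taken over all exonic bases, while the kit reads 3' ends. Low counts of such genes may therefore not be low expression, and no biological explanation was tested.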
